A study of Mus musculus with 9 samples.

How the data were processed

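Messenger RNA was sequenced from RAW264.7 cells, an established mouse macrophage-like cell line, in 9 libraries that the labels place in 3 groups of 3: NC, HG (35 mmol/l glucose for 6 h) and HG-SIG (35 mmol/l glucose with sitagliptin phosphate for 6 h). Groups and replicate numbers were taken from the sample titles, and glucose concentration and time from the series' design text. Neither gives a glucose concentration or an incubation time for NC, which was treated here as the control. The labels give a single batch for all 9 samples. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads, and cDNA was made with random hexamer primers after fragmentation.

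The deposited values were gene counts, 1 column per library. Per the submitters' processing notes, Bowtie2 2.3.5, RSEM and the genome build mm10 were used; the annotation release, read length and strand setting are not given in the sources used here. All deposited counts were whole numbers (100%), so counts estimated by RSEM could have been rounded before deposit, and they were tested as they stood. The table held 20627 features, of which 18631 had an Ensembl gene identifier and 1996 were unannotated loci without a gene name. Of the Ensembl identifiers, 18591 were found in GENCODE M21 (GRCm38, the same assembly as mm10), which supplied coordinates, exon length, GC content and gene type, and 40 were not. The unannotated loci took 5.85% to 6.21% of the counts of a library. They stayed in the tests. The rule for named genes took none of them, and 1 was added after its values were seen.

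Library totals ranged from 23285821 to 31571578 counts, so a floor of 3 counts corresponded to 0.095 to 0.129 CPM, counts scaled to a common library total. For genes with few counts, ratios between groups are given with the exact 95% counting interval. A floor of 3 counts over the group stands in for a group at 0 and leaves out the counting error of the other group, which the lower end of the interval includes. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Nothing in the labels says that the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

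Counts were filtered with edgeR's filterByExpr by group, which left 13311 genes, scaled with TMM and fitted with edgeR 4.0.16 in R 4.3.3 as 1 model with a mean per group over all 9 libraries. HG against NC, HG-SIG against HG and HG-SIG against NC were tested with the quasi-likelihood F-test, adjusted with the Benjamini-Hochberg method over all genes tested, and called at an adjusted p under 0.05. Every adjusted p of a gene in the text comes from this test unless another is named. The number of called genes with an absolute log2 fold change over 1, the criterion the series states, was counted beside it. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are TMM-scaled CPM, given as mean ± SD with n = 3 libraries per group.

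Gene lists were fixed before the data were examined: 35 lists for macrophage polarization, inflammation, glucose and lipid metabolism, stress responses, signalling, other cell types and RNA composition. Lists with 5 or more tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison, and again with an estimated correlation. Members called were counted over all genes tested and adjusted over the list alone. For fry and for the alternatives the same lists were used.

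Genes were named by a rule fixed before the data were examined. For each comparison it took the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of 2 or more, no overlap between the libraries of the groups and an established symbol. It added up to 4 members of each list by p-value, 16 genes to be reported whatever their result, and up to 6 genes called in opposite directions in HG against NC and HG-SIG against HG. List members named in the text as exceptions to their list's direction, and Akr1b3 and Slc6a6, were chosen after their values were seen. In all, the rule and these additions gave 171 genes, not all of which are described; 17 of them overlap another gene of the table over more than 10% of their exonic length, and the strand used in counting is not given, so their values may include reads of the other gene.

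Scripts were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. In the simulated HG against NC comparison, run on 13171 genes, the edgeR test recovered 67.7% of genes changed by 0.5 on the log2 scale and 83% of those changed by 1, with 4.5% of its calls false. In the simulated HG-SIG against HG comparison without any change it made 0 calls, as did DESeq2 and limma-voom. The list test called 0 of 40 unchanged lists in the simulated HG against NC comparison. Genes were simulated without correlation between them, so this does not show how often lists of correlated genes are called falsely.

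Replicate numbers are shared by the groups in the titles, without any statement that they mark a shared day or culture. Correlations of the deviations from group means were 0.243, 0.289 and 0.467 for the same-numbered HG and HG-SIG libraries, all above the 0.1 set for pairing. For NC with HG they were 0.093, 0.233 and 0.293, and for NC with HG-SIG 0.097, 0.133 and 0.211. Only the NC values of replicate 1 were under 0.1, and the numbers were taken to pair HG with HG-SIG libraries. Of 18 best matches between libraries of different groups 17 were to the same number, NC libraries included, so a pairing of NC stays possible. Any such pairing comes from the data, not from the labels. The fit with the replicate number as a block was run as an alternative.

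Other alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), near the limma analysis of log2 TPM that the series states, limma-voom, no filter, a filter on average log2 CPM, only the 6 samples compared, stricter thresholds and leaving out each library in turn. TPM were computed here from the deposited counts and exon lengths. Scaling by library size alone, removal of each library's trend with GC content and length, thinning to the lowest library total and leaving out the unannotated loci were chosen after seeing the data. Because both main comparisons share the HG libraries, 50 sets of unchanged groups were simulated to give the covariance of fold changes that sharing alone produces. Calls in these sets were counted too. A further 50 sets, added after seeing the data, had same-numbered libraries correlated as measured. Of the 16 genes to be reported whatever their result, Cd163, Dpp4 and Glp1r were not analysed here.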

Results

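The series sequenced polyadenylated RNA from RAW264.7 mouse macrophages in 3 groups of 3 libraries: NC, the control; HG, exposed to 35 mmol/l glucose for 6 h; and HG-SIG, exposed for 6 h to the same glucose concentration with sitagliptin phosphate. Sitagliptin inhibits dipeptidyl peptidase 4 and is used against type 2 diabetes. The series title places the experiment in the study of macrophage polarization and inflammation in diabetes. None of the groups held an osmotic control or sitagliptin without added glucose. Library totals were 31571578, 25527773 and 31547760 counts for NC replicates 1 to 3. They were 29543475, 26531302 and 23285821 for HG and 29232106, 28886288 and 30752927 for HG-SIG.

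The first principal component of log2 CPM held 53.4% of the variance and ordered the groups NC, HG and HG-SIG; the second held 15.9% and set HG apart from both others. HG replicate 3 stood apart from the other HG libraries on the third component, which held 7.4%. The gene with the highest share of counts, mitochondrial mt-Co1, took 1.27% to 1.47% in each library. Mitochondrially encoded genes took 3.72 ± 0.256% of counts in NC, 3.94 ± 0.099% in HG and 3.91 ± 0.082% in HG-SIG, and ribosomal protein genes 4.12 ± 0.142%, 4.11 ± 0.266% and 3.85 ± 0.123% (SD, n = 3). Replicates of a group differed by more than counting noise, with 2.85 to 9.45 chi-square units per gene. Markers of other cell types were scarce. Of the epithelial list 4 of 7 genes were in the table, of the T and B lymphocyte list 7 of 12, and 0 of either had enough counts to be tested.

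HG was compared with NC to ask what high glucose changed in these macrophages. Inflammatory genes were lower in HG. Tnf, the gene for the cytokine tumour necrosis factor, went from 194 ± 5.54 CPM in NC to 40.9 ± 2.46 CPM in HG (SD, n = 3), a log2 fold change of -2.24 ± 0.06 (SE, adjusted p = 4.9e-11). All 24 tested NF-kB target genes fell, and so did 26 of 27 targets of ATF4, the transcription factor of the integrated stress response. Genes of cholesterol synthesis and of the cell cycle rose by smaller amounts, as lists that did not pass with an estimated correlation (adjusted p = 0.0614 and 0.168). The myo-inositol transporter gene Slc5a3, which serves the uptake of an osmolyte, rose from 148 ± 5.46 to 373 ± 53.5 CPM (log2 fold change 1.33 ± 0.10, adjusted p = 8.6e-07). Of the 13311 genes tested, 3927 were called, 1899 higher and 2028 lower in HG, with a median absolute log2 fold change of 0.29. Of these, 379 changed by more than 1 on the log2 scale, 83 up and 296 down. The libraries of the groups did not overlap for 41.7% of genes, where chance gives 10%.

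Among called genes with an average log2 CPM of 2 or more, no overlap between the libraries of the groups and an established symbol, the highest was Ranbp3l (ENSMUSG00000048424, chromosome 15, 8967949 to 9067335 in mm10), at 13.7 ± 3.93 CPM in NC and 86.6 ± 12.3 CPM in HG (log2 fold change 2.67 ± 0.15, adjusted p = 4.2e-08). The others of the 8 highest were Grtp1 (1.73), Trp53i11 (1.67), the ether lipid monooxygenase Agmo (1.49), Rnf144b (1.45), the pro-apoptotic Bmf (1.41), the retinoic acid receptor gene Rarb (1.38) and Slc5a3. Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), whose enzyme makes the immunometabolite itaconate, was the lowest at 55.4 ± 1.15 CPM in NC and 3.69 ± 0.817 CPM in HG (-3.89 ± 0.11, adjusted p = 1.0e-10). It was followed among these genes by the neutrophil chemokine gene Cxcl2 (-3.61), the transcription factor Myc (-2.88), the glutathione-degrading Chac1 (-2.88), Lilr4b (-2.77), lymphotoxin beta Ltb (-2.56), the G protein regulator Rgs16 (-2.56) and the ERK phosphatase gene Dusp5 (-2.55).

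Among genes reported whatever their result, Nos2, the inducible nitric oxide synthase of classically activated macrophages, had 67 counts in the 3 NC libraries and 9 in HG (log2 fold change -2.73 ± 0.45, adjusted p = 9.3e-04). Il1b had 52 counts in NC and 2 in HG, a ratio of 23.7 with a counting interval of 6.25 to 201. Ptgs2, the inducible cyclooxygenase, fell from 102 to 49.7 CPM (-1.04 ± 0.12), the monocyte chemokine gene Ccl2 from 8.23 to 4.17 CPM (-0.99 ± 0.16), Tgfb1 from 214 to 135 CPM (-0.67 ± 0.03) and the inflammasome sensor gene Nlrp3 from 142 to 71.1 CPM (adjusted p = 1.8e-08). Txnip, a glucose-responsive gene, rose from 261 ± 28.0 to 339 ± 33.8 CPM (0.38 ± 0.09, adjusted p = 0.00633). Il6 had at most 1 count per library and allows no fold. The M2-type markers Mrc1 (10 counts in NC, 2 in HG, ratio 4.57 with an interval of 0.973 to 42.9) and Arg1 (6 and 4 counts, ratio 1.37, 0.325 to 6.6), the costimulatory Cd86 (16 and 8, ratio 1.83, 0.738 to 4.93) and the anti-inflammatory cytokine gene Il10 (37 and 15, ratio 2.25, 1.21 to 4.42) stayed below the filter and were not tested. These intervals leave out the spread between replicates.

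**Figure D1:**
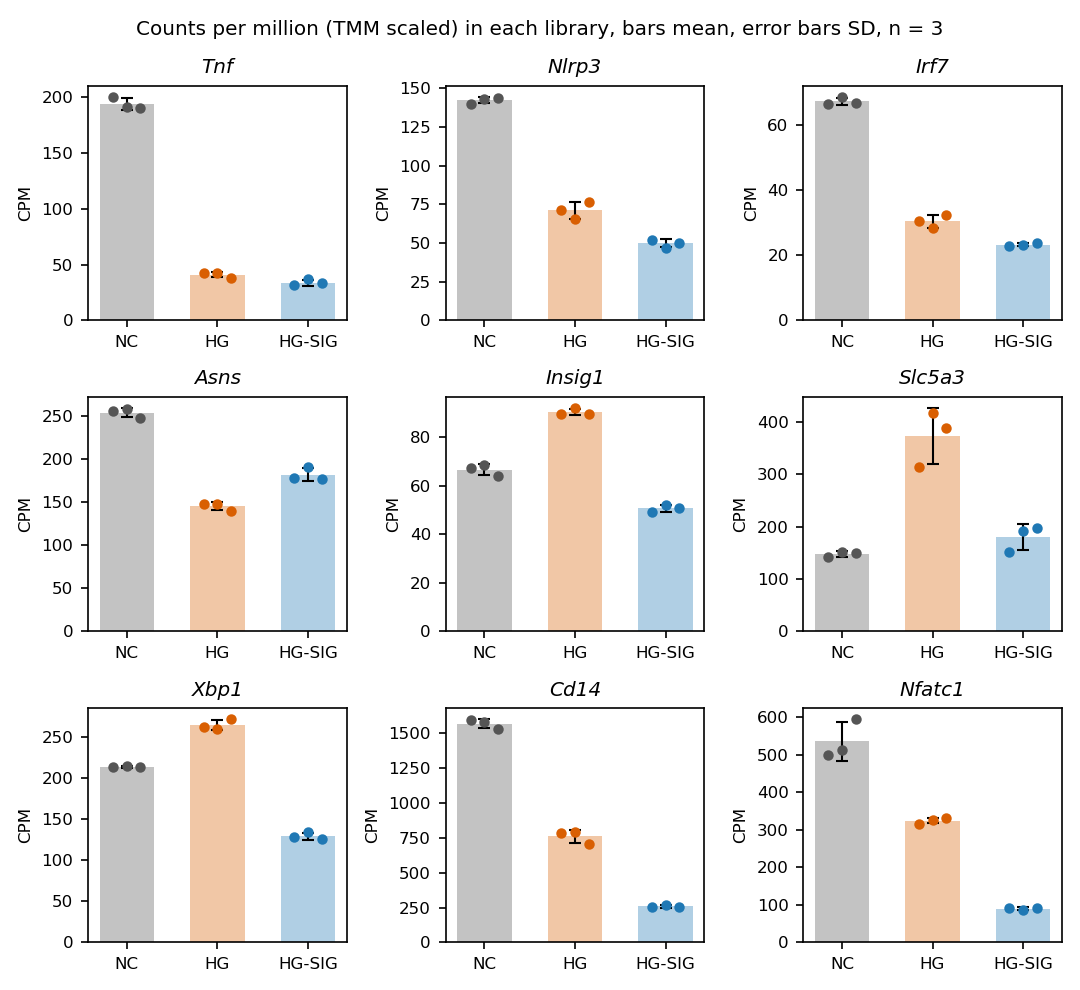
TMM-scaled CPM of 9 genes in each library, with bars for the mean and error bars for the SD (n = 3 per group). Tnf fell from 194 in NC to 40.9 in HG, and Slc5a3 rose to 373 in HG and stood at 180.4 in HG-SIG.

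The NF-kB list, which holds feedback inhibitors and targets of this inflammatory transcription factor, was lower in HG: 0 of 24 rose, 24 fell and 0 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change -1.09, camera adjusted p = 3.4e-64, adjusted p = 1.6e-04 with an estimated correlation). The precursor gene Nfkb2 fell by 1.29 on the log2 scale, Tnfaip2 by 1.27, the apoptosis inhibitor Birc3 by 1.14 and the feedback inhibitor Tnip1 by 1.04. Of the M1-type markers, which mark pro-inflammatory macrophages, 1 of 12 rose, 11 fell and 0 did not pass the test, again with the same counts adjusted over the list alone (median log2 fold change -1.75, camera adjusted p = 1.6e-15, adjusted p = 0.00926 with an estimated correlation). Cxcl10 had a log2 fold change of -1.74, Socs3 -1.58 and Cd40 -3.12, while the Fc receptor gene Fcgr1 rose (0.42). M2-type markers, which mark alternatively activated macrophages, were also lower: 0 of 10 rose, 6 fell and 4 did not pass the test, equally when adjusted over the list alone (median log2 fold change -0.35, camera adjusted p = 4.3e-05, adjusted p = 0.0199 with an estimated correlation). They included the interleukin 1 receptor antagonist Il1rn (-0.92), the transglutaminase Tgm2 (-1.30) and Tgfb1.

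Interferon-stimulated genes, the antiviral effectors, fell in HG: 0 of 28 rose, 26 fell and 2 did not pass the test, and 0 rose and 27 fell when adjusted over the list alone (median log2 fold change -0.93, camera adjusted p = 2.0e-35, adjusted p = 0.0111 with an estimated correlation). Irf7, which drives type I interferon genes, went from 67.3 ± 1.13 to 30.4 ± 1.99 CPM (-1.15 ± 0.05, adjusted p = 3.3e-09), with Ddx58 (-1.24), a sensor of viral RNA, Dhx58 (-1.17) and Parp14 (-1.25). Of the chemokines and chemokine receptors, 0 of 14 rose, 10 fell and 4 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change -1.23, camera adjusted p = 6.9e-11, adjusted p = 0.00926 with an estimated correlation). Ccl9 fell from 529 to 223 CPM (-1.25) and Ccl3 by 1.22 on the log2 scale. In the immediate-early list 1 of 27 rose, 17 fell and 9 did not pass the test, and 1 rose and 20 fell when adjusted over the list alone (median log2 fold change -0.38, camera adjusted p = 1.1e-14, adjusted p = 0.0245 with an estimated correlation). Junb (-0.83), the ERK phosphatase gene Dusp4 (-0.93), Ier3 (-1.73) and Myc fell, and Klf2 rose (0.64). Of the NLRP3 inflammasome genes 2 of 12 rose, 6 fell and 4 did not pass the test, and 2 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.00563, adjusted p = 0.192 with an estimated correlation). Those that fell included Nlrp3 and Casp4 (-1.36), an inflammatory caspase gene.

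ATF4 targets, which serve amino acid supply and stress adaptation, were lower in HG: 1 of 27 rose, 26 fell and 0 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change -0.64, camera adjusted p = 1.8e-30, adjusted p = 9.5e-04 with an estimated correlation). Asparagine synthetase Asns fell from 254 ± 5.19 to 146 ± 4.62 CPM (-0.80 ± 0.04, adjusted p = 1.5e-08), as did the mitochondrial folate enzyme Mthfd2 (-0.83), the translation repressor Eif4ebp1 (-0.89) and Chac1, whereas the serine synthesis gene Psat1 rose (0.17). Glycolysis genes moved less: 0 of 24 rose, 10 fell and 14 did not pass the test, equally when adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 0.0088, adjusted p = 0.468 with an estimated correlation). The phosphofructokinase Pfkp (-0.70) and the glucose transporter Slc2a1 (from 338 to 169 CPM) fell. HIF-1 targets outside glycolysis were lower as well: 0 of 23 rose, 15 fell and 8 did not pass the test, and 0 rose and 17 fell when adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 4.4e-06, adjusted p = 0.376 with an estimated correlation). Ero1a (-0.70), Anxa2 (-0.54) and Bhlhe40 (-0.85) fell.

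Cholesterol synthesis and SREBP2 target genes rose in HG: 17 of 23 rose, 0 fell and 6 did not pass the test, and 18 rose and 0 fell when adjusted over the list alone (median log2 fold change 0.33, camera adjusted p = 4.6e-11, adjusted p = 0.0614 with an estimated correlation). The sterol sensor gene Insig1 went from 66.6 ± 2.25 to 90.3 ± 1.38 CPM (0.44 ± 0.04), with the synthesis genes Dhcr7 (0.59) and Mvd (0.66). Cell cycle and replication genes also rose: 28 of 35 rose, 0 fell and 7 did not pass the test, and 29 rose and 0 fell when adjusted over the list alone (median log2 fold change 0.17, camera adjusted p = 6.4e-08, adjusted p = 0.168 with an estimated correlation). Examples were the replicative helicase subunit Mcm7 (0.32 ± 0.03), the cyclin Ccna2 (0.31) and the spindle checkpoint kinase Bub1b (0.32). In the NFAT5 list of hyperosmotic response genes, 5 of 15 rose, 4 fell and 6 did not pass the test, and 6 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.692). The betaine transporter Slc6a12 (1.09 ± 0.09, from 174 to 371 CPM), the sorbitol-producing aldose reductase Akr1b3 (0.46) and the heat-shock gene Hspa1b (1.27) rose with Slc5a3, the taurine transporter gene Slc6a6 had a log2 fold change of 0.05 (adjusted p = 0.563), and the fatty acid receptor gene Gpr84 fell (-1.81). LXR and lipid-handling genes went both ways (7 of 19 rose and 5 fell, 7 and 6 adjusted over the list alone, camera adjusted p = 0.204). The lysosomal acid lipase Lipa (0.73) and the desaturase Scd1 (0.54) rose, and the scavenger receptor Cd36 fell (-0.66).

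Monocyte and macrophage identity markers were somewhat lower in HG: 4 of 19 rose, 8 fell and 7 did not pass the test, and 4 rose and 9 fell when adjusted over the list alone (median log2 fold change -0.14, camera adjusted p = 0.00247, adjusted p = 0.0423 with an estimated correlation). Cd14, the coreceptor for lipopolysaccharide, fell from 1567 ± 32.6 to 759 ± 46.5 CPM (-1.05 ± 0.05, adjusted p = 5.3e-09), the inhibitory Fc receptor gene Fcgr2b by 1.18 and the phagocyte oxidase gene Cybb by 0.54 on the log2 scale. Of the osteoclast differentiation markers, to which RAW264.7 cells can be driven, 1 of 9 rose, 5 fell and 3 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 0.00267, adjusted p = 0.0482 with an estimated correlation). The fusion gene Dcstamp (-1.42), the protease Mmp9 (-3.00) and the osteoclast transcription factor Nfatc1 (-0.72) fell, and carbonic anhydrase Car2 rose (0.83). In the lysosome and phagocytosis list 3 of 25 rose, 12 fell and 10 did not pass the test, and 5 rose and 12 fell when adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.0249, adjusted p = 0.358 with an estimated correlation). The autophagy receptor gene Sqstm1 (-0.62) and the protease gene Ctsl (-0.50) fell. Without HG replicate 1 the lysosome list no longer passed (adjusted p = 0.059).

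The remaining lists did not pass in HG against NC. Rises and falls were 3 and 1 of 10 for ChREBP and MondoA glucose-responsive genes, among them the fatty acid synthase Fasn (0.44) and Txnip (camera adjusted p = 0.429), 3 and 1 of 12 for the pentose phosphate and polyol pathways (0.188). They were 4 and 1 of 21 for the tricarboxylic acid cycle (0.574), 2 and 0 of 39 for oxidative phosphorylation (0.237) and 2 and 4 of 21 for the unfolded protein response (0.905). Counts were 4 and 6 of 25 for NRF2 antioxidant genes (0.912, by library size alone 8 and 6) and 2 and 0 of 16 for heat-shock proteins (0.385). For p53 targets they were 1 and 4 of 16 (0.385), for insulin and PI3K signalling 2 and 4 of 19 (0.634), and for MAPK and Toll-like receptor signalling 3 and 7 of 27 (0.188). Adjusted over the list alone, 3 rose and 1 fell in the tricarboxylic acid cycle, 0 and 0 in oxidative phosphorylation and 1 and 5 among p53 targets, and the other counts of these lists were the same. The tricarboxylic acid cycle list had a median of 0.04 and a mean of -0.14, since it holds Acod1, and the p53 list a median of 0.01 and a mean of -0.16. Without HG replicate 3 the oxidative phosphorylation list (adjusted p = 0.00928) and the pentose phosphate and polyol list (0.0278) passed, both higher. Cytosolic ribosomal protein genes (1 of 35 rose, 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.912), mitochondrially encoded genes (2 of 13 rose, 1 adjusted over the list alone, 0.394) and histone genes (2 of 6 rose, 0.241) did not pass either. Lists too small for a test were the DPP family and incretin receptors (0 of 4 rose, 0 fell), dendritic cell markers (0 of 3 rose, 2 fell) and fibroblast markers (0 of 2 rose, 0 fell). Scaled by library size alone, 58.9% of 4212 calls were higher in HG (2480 up, 1732 down), against 48.4% with TMM, and with limma on log2(TPM + 1) 59.2% were.

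HG-SIG was compared with HG, the comparison the series names, to ask what sitagliptin changed under high glucose. Genes of macrophage identity, osteoclast differentiation, lipid handling and the unfolded protein response were lower with sitagliptin. Cd14 fell again, from 759 ± 46.5 CPM in HG to 258 ± 9.05 CPM in HG-SIG (SD, n = 3; log2 fold change -1.56 ± 0.05 SE, adjusted p = 9.3e-11). The fractalkine receptor gene Cx3cr1 fell from 378 ± 22.3 to 76.9 ± 7.40 CPM (-2.30 ± 0.07, adjusted p = 6.3e-11). The scavenger receptor gene Msr1 fell from 376 ± 7.91 to 116 ± 3.63 CPM (-1.69 ± 0.04, adjusted p = 9.8e-12). Tnf changed by -0.27 ± 0.06 (adjusted p = 0.00211), far less than between HG and NC. Of the 13311 genes 6989 were called, 3417 higher and 3572 lower in HG-SIG, with a median absolute log2 fold change of 0.33, and 706 of them changed by more than 1 on the log2 scale, 288 up and 418 down. The libraries of the groups did not overlap for 58.7% of genes, where chance gives 10%.

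The split between rises and falls depended on the scaling. Scaled by library size alone, the median of all genes moved up by 0.17 on the log2 scale and 76.9% of 7919 calls were higher in HG-SIG (6093 up, 1826 down), against 48.9% with TMM; with limma on log2(TPM + 1) the shift was 0.19 and 81.9% were higher. The changes given here are therefore relative to the typical gene. Log2 fold changes also fell with expression level in HG-SIG against HG, with a Spearman correlation with average log2 CPM of -0.25. In HG against NC it was 0.03, and in HG-SIG against NC -0.20. No alternative removed this trend, and its part in the falls of lists of highly expressed genes against HG or NC was not tested.

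Among genes that met the same limits, the largest falls were in Xirp1 (ENSMUSG00000079243, chromosome 9, 120013755 to 120023598; 10.5 CPM in HG, 0.477 in HG-SIG, log2 fold change -4.44 ± 0.17, adjusted p = 5.4e-10), Rgs16 (ENSMUSG00000026475, chromosome 1, 153740349 to 153745468; 32.8 ± 2.05 and 1.63 ± 0.275 CPM, -4.33 ± 0.10, adjusted p = 9.8e-12) and the CD30 ligand gene Tnfsf8 (-4.10). The decoy receptor Il13ra2 (-3.70), Myc (-3.46 ± 0.29; 2.57 CPM in HG, 0.230 in HG-SIG), Angptl2 (-3.31), Olfml3 (-3.14) and the matrix protein gene Tnc (-2.67) completed the 8 lowest of them. Zrsr1 rose the most of them, from 1.97 ± 0.276 to 8.98 ± 0.239 CPM (2.19 ± 0.12, adjusted p = 1.4e-08). Also among the 8 highest were L3mbtl3 (1.78), Mob3b (1.57), the lipid-sensing nuclear receptor Ppard (1.47, from 5.41 to 14.9 CPM), the neutral amino acid transporter Slc1a4 (1.45), Hip1r (1.43) and Fam214a (1.40).

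Nos2 had 9 counts in HG and 0 in HG-SIG, at least 2.47-fold lower by the counting interval and 3.76-fold against a floor of 3 counts over the group. Il1b had 2 and 6 counts, a ratio of HG over HG-SIG of 0.417 with a counting interval of 0.0412 to 2.33. Ptgs2 fell from 49.7 to 12.2 CPM (-2.04 ± 0.14, adjusted p = 1.4e-07) and Nlrp3 from 71.1 to 49.8 CPM (-0.51 ± 0.05). Smaller falls were called for Tgfb1 (-0.16 ± 0.03), Tnf and Ccl2 (-0.55 ± 0.18, adjusted p = 0.0194). Scaled by library size alone Tnf (-0.11), Ccl2 (-0.39) and Tgfb1 (0.00) were not called, and Ccl2 was not called without HG replicate 2 (adjusted p = 0.0602) or HG-SIG replicate 3 (0.0749). Txnip did not pass (0.07 ± 0.09, adjusted p = 0.513), but did in the fit with the replicate number as a block (adjusted p = 0.0447) and when scaled by library size alone (0.23, adjusted p = 0.0394). Il10 had 15 counts in HG and 3 in HG-SIG, a ratio of 6.26 with an interval of 1.77 to 33.7, and Arg1 had 4 and 0, with an interval that starts at 0.827 and so leaves a difference open. Mrc1 had 2 and 6 counts (ratio of HG over HG-SIG 0.417, interval 0.0412 to 2.33), Cd86 8 and 28 (0.358, 0.141 to 0.806), and Il6 0 and 1, which allows no fold.

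Macrophage identity markers fell in HG-SIG: 1 of 19 rose, 17 fell and 1 did not pass the test, and 1 rose and 18 fell when adjusted over the list alone (median log2 fold change -0.79, camera adjusted p = 1.8e-23, adjusted p = 0.00116 with an estimated correlation). The pore-forming Mpeg1 (-1.18), lysozyme Lyz1 (-0.94, from 5066 to 2645 CPM) and Cybb (-0.87) fell with Cd14, and the Fc receptor gene Fcgr3 rose (0.47). Of the osteoclast markers 0 of 9 rose, 8 fell and 1 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change -1.49, camera adjusted p = 1.5e-16, adjusted p = 0.00171 with an estimated correlation). Nfatc1 went from 324 ± 7.78 to 89.8 ± 3.62 CPM (-1.85 ± 0.06, adjusted p = 1.8e-10), the RANKL receptor Tnfrsf11a from 203 to 66.7 CPM (-1.61), and tartrate-resistant acid phosphatase Acp5 (-1.49) and Car2 (-1.52) fell. LXR and lipid-handling genes were lower: 1 of 19 rose, 16 fell and 2 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 5.3e-11, adjusted p = 0.00925 with an estimated correlation). Besides Msr1, lipoprotein lipase Lpl (-1.26, from 1402 to 586 CPM), Cd36 (-1.52 ± 0.06) and Lipa (-0.47) fell, and the acyl-CoA synthetase Acsl1 rose (0.35). In the lysosome list 2 of 25 rose, 19 fell and 4 did not pass the test, and 3 rose and 19 fell when adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 8.6e-08, adjusted p = 0.0737 with an estimated correlation). The macrophage marker Cd68 (-0.74), Gpnmb (-0.82) and the protease Ctsd (-0.60) fell, and the cholesterol transporter Npc1 rose (0.34).

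**Figure D2:**
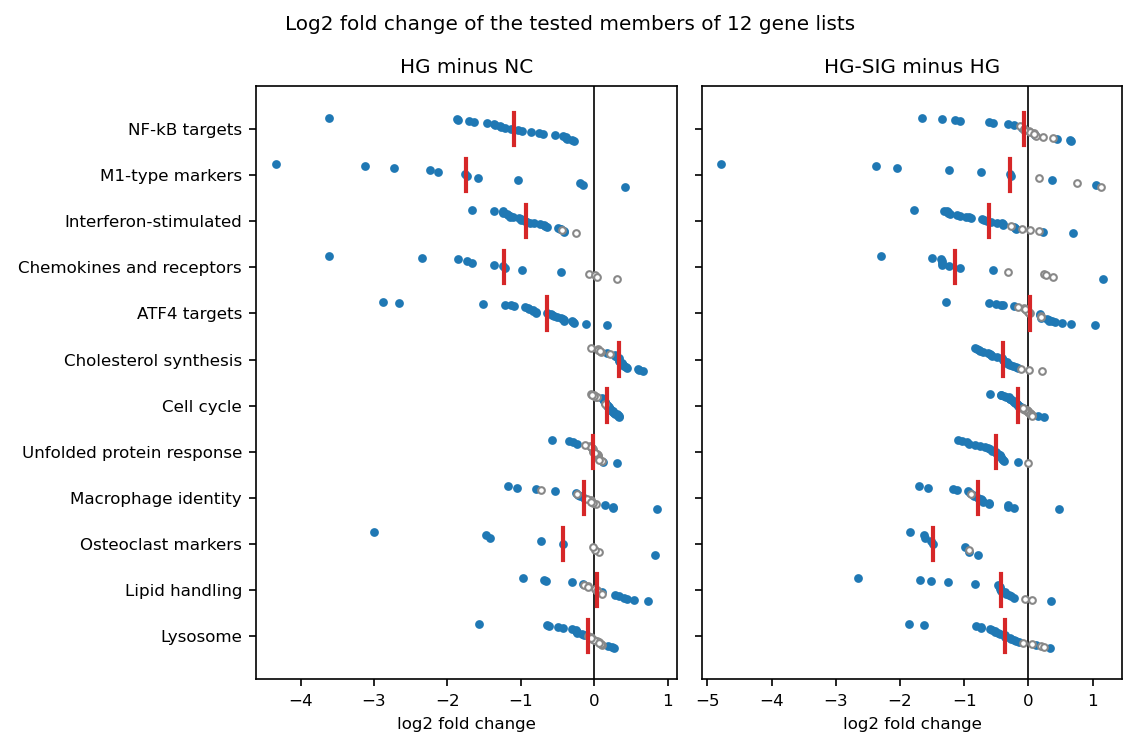
Log2 fold changes of the tested members of 12 gene lists in HG minus NC (left) and HG-SIG minus HG (right), with TMM scaling. Each point is a gene, filled where its adjusted p was under 0.05, and red lines mark list medians, such as -1.09 (left) and -0.07 (right) for NF-kB targets, where scaling by library size alone gave 0.09 on the right.

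Genes of the unfolded protein response in the endoplasmic reticulum fell almost throughout: 0 of 21 rose, 20 fell and 1 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 5.7e-20, adjusted p = 0.00547 with an estimated correlation). The transcription factor Xbp1 went from 265 ± 6.27 to 129 ± 4.20 CPM (-1.03 ± 0.04, adjusted p = 2.5e-10) and the chaperone Hspa5 from 1813 to 1012 CPM (-0.84 ± 0.04), with Herpud1 (-1.09) and Edem1 (-0.76), both of the degradation of misfolded proteins. Cholesterol synthesis genes were lower as well: 0 of 23 rose, 20 fell and 3 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.40, camera adjusted p = 9.6e-10, adjusted p = 0.103 with an estimated correlation). Insig1 (-0.84), squalene synthase Fdft1 (-0.80), Msmo1 (-0.71) and Hmgcs1 (-0.58) fell. Glycolysis genes were lower: 1 of 24 rose, 16 fell and 7 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.32, camera adjusted p = 2.5e-04, adjusted p = 0.396 with an estimated correlation). They included lactate dehydrogenase Ldha (-0.52, from 2401 to 1677 CPM), pyruvate kinase Pkm (-0.48), Hk1 (-0.51) and Eno1b (-0.56), while Pfkm rose (0.31). In the NFAT5 list 2 of 15 rose, 9 fell and 4 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 0.00861, adjusted p = 0.396 with an estimated correlation). Slc5a3 fell from 373 ± 53.5 to 180.4 ± 24.5 CPM (-1.05 ± 0.10, adjusted p = 3.5e-06), as did Slc6a12 (-0.49), Akr1b3 (-0.36), Akr1b8 (-1.29), the water channel Aqp1 (-3.44) and Gpr84 (-0.70). Slc6a6 was called lower with TMM (-0.16) but not when scaled by library size alone (0.00), nor without HG replicate 3 (adjusted p = 0.0796), HG-SIG replicate 1 (0.107) or HG-SIG replicate 2 (0.065).

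Of the M1-type markers 2 of 12 rose, 7 fell and 3 did not pass the test with TMM, while 4 rose and 5 fell by library size alone, with a median of -0.12. With TMM the counts were the same adjusted over the list alone and the list did not pass (median log2 fold change -0.28, camera adjusted p = 0.0555, adjusted p = 0.396 with an estimated correlation). Without HG-SIG replicate 1 it did (adjusted p = 0.0402). Irf5, a transcription factor of inflammatory macrophages, fell from 192 to 115 CPM (-0.74 ± 0.04), as did Ptgs2, while Irf1 (0.37) and the costimulatory Cd80 (1.05) rose. Of the M2-type markers 2 of 10 rose, 8 fell and 0 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.55, camera adjusted p = 0.0399, adjusted p = 0.205 with an estimated correlation). It did not pass without HG replicate 1 (adjusted p = 0.0587). Il1rn (-1.60) and the beta-glucan receptor Clec7a (-1.03) fell and the interleukin 4 receptor gene Il4ra (0.97) and Irf4 (1.29) rose, both from low levels. The NF-kB list, all of which had fallen in HG, went both ways: 4 of 24 rose, 10 fell and 10 did not pass the test, the same adjusted over the list alone (median -0.07, 0.09 when scaled by library size alone with 10 up and 6 down, camera adjusted p = 0.177). The NF-kB inhibitor gene Tnip3 (-1.66) and Traf1 (-1.14) fell and Tnfaip2 rose (0.67). Interferon-stimulated genes were lower: 2 of 28 rose, 22 fell and 4 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.61, camera adjusted p = 4.6e-06, adjusted p = 0.308 with an estimated correlation). Rtp4 (-1.25), Usp18 (-1.32), Oasl1 (-0.93) and Ifi44 (-0.90) fell, and Ifit2 (0.69) and the RNA sensor Ifih1 (0.23) rose. The Ifih1 call was lost without HG replicate 2 (adjusted p = 0.0852). Chemokines and their receptors were lower: 1 of 14 rose, 9 fell and 4 did not pass the test, the same adjusted over the list alone (median log2 fold change -1.15, camera adjusted p = 2.2e-10, adjusted p = 0.0148 with an estimated correlation). They included Cx3cr1, Cxcl16 (-1.50), Ccl9 (-1.34) and Cxcl14 (-1.36). The exception, Ccrl2 (1.16, adjusted p = 0.0473), was not called in the fit with the replicate block (adjusted p = 0.0529) or without any 1 of 7 libraries, with HG-SIG replicate 1 left out giving the highest adjusted p (0.184).

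In the immediate-early list 2 of 27 rose, 12 fell and 13 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.16, camera adjusted p = 0.0145, adjusted p = 0.46 with an estimated correlation, and a median of 0.00 when scaled by library size alone, with 8 up and 11 down). With the GC and length trend removed the list did not pass (adjusted p = 0.0509). Dusp4 (-1.11), Junb (-0.60) and Fosl2 (-0.67) fell, and the antiproliferative Btg2 rose (1.05). Cell cycle genes were lower: 2 of 35 rose, 21 fell and 12 did not pass the test, and 2 rose and 22 fell when adjusted over the list alone (median log2 fold change -0.16, camera adjusted p = 0.00976, adjusted p = 0.493 with an estimated correlation). Scaled by library size alone 12 rose and 10 fell, their median was 0.00 and the list did not pass (adjusted p = 0.232). Examples were the replication licensing factor Cdc6 (-0.60), Mcm7 (-0.43) and Mcm3 (-0.38). Of NRF2 antioxidant genes 5 of 25 rose, 13 fell and 7 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 0.0145, adjusted p = 0.57 with an estimated correlation). The cystine transporter Slc7a11 (-1.28), heme oxygenase Hmox1 (-0.83) and Gpx1 (-0.67) fell. Scaled by library size alone 8 and 8 rose and fell, and the NRF2 list did not pass (adjusted p = 0.0548). ATF4 targets went both ways: 11 of 27 rose, 6 fell and 10 did not pass the test, the same adjusted over the list alone (camera adjusted p = 0.6). Atf4 itself (-0.42) and Slc7a11 fell and the stress sensor Sesn2 rose (1.03). Insulin and PI3K-Akt-mTOR genes were the list that rose: 10 of 19 rose, 1 fell and 8 did not pass the test, the same adjusted over the list alone (median log2 fold change 0.15, camera adjusted p = 0.0352, adjusted p = 0.493 with an estimated correlation). The list did not pass without HG replicate 1 (adjusted p = 0.0724) or with the GC and length trend removed (0.131). Foxo1 (0.63) and Gsk3b (0.32) rose, both restrained by Akt signalling. Akt1 fell with TMM (-0.15) but not when scaled by library size alone (0.01), nor without HG replicate 2 (adjusted p = 0.0563) or HG-SIG replicate 2 (0.0502).

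Cytosolic ribosomal protein genes were lower in HG-SIG: 0 of 35 rose, 31 fell and 4 did not pass the test, and 0 rose and 33 fell when adjusted over the list alone (median log2 fold change -0.27, camera adjusted p = 2.6e-04, adjusted p = 0.493 with an estimated correlation; with scaling by library size alone a median of -0.11, with 9 lower). Rps6 (-0.68) and Rpl5 (-0.31) were among them. Oxidative phosphorylation genes were lower too with TMM, but not by library size alone, where 3 rose, 2 fell and the median was -0.01. With TMM 0 of 39 rose, 24 fell and 15 did not pass the test, the same adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 0.0247, adjusted p = 0.686 with an estimated correlation). An example was Ndufb3 (-0.30). The oxidative phosphorylation list did not pass when scaled by library size alone (adjusted p = 0.133), with the GC and length trend removed (0.199) or without HG replicate 1 (0.0591), HG replicate 2 (0.0878) or HG-SIG replicate 3 (0.0654). The other lists did not pass. Rises and falls were 5 and 2 of 12 for NLRP3 inflammasome genes, with Nlrp3 and the pore protein Gsdmd (-0.91) lower (camera adjusted p = 0.82), 3 and 9 of 23 for HIF-1 targets (0.424; 7 and 6 by library size alone), 0 and 3 of 10 for ChREBP and MondoA genes (0.419, by library size 4 and 2) and 3 and 6 of 12 for the pentose phosphate and polyol pathways (0.27, by library size 4 and 4). For the tricarboxylic acid cycle they were 3 and 11 of 21 (0.18, by library size 9 and 5), for heat-shock proteins 4 and 5 of 16 (0.82, by library size 10 and 1), and for mitochondrially encoded genes 0 and 8 of 13 (0.177, by library size 1 and 1). p53 targets split evenly, with 6 up, such as Trp53inp1 (1.87), Ccng1 (0.53) and Btg2, and 6 down, such as Sesn1 (-0.74), of 16 (0.34, median -0.04, 0.12 when scaled by library size alone with 7 up and 3 down, mean 0.19). MAPK and Toll-like receptor genes had 11 up and 7 down of 27 (0.505, median 0.09, mean -0.02), with Tlr7 (-1.19) and Cd14 lower. Of the histone genes 2 of 6 rose, H1f2 (0.78) and H2bc4 (0.76), and 0 fell (0.327). Adjusted over the list alone, 4 pentose phosphate and polyol genes rose and 6 fell, 9 mitochondrially encoded genes fell, 2 dendritic cell markers rose, and the other counts of these lists were the same. Among lists too small for a test, 0 of 4 DPP family genes rose and 2 fell with TMM, against 2 and 0 by library size alone, while 1 of 3 dendritic cell markers rose and 1 fell (2 and 1 by library size), and 1 of 2 fibroblast markers fell. The latter was Acta2, from 0.341 to 0.145 CPM (-1.20, adjusted p = 0.0289), a call lost without HG replicate 2 (0.0961) or 3 (0.0628), or HG-SIG replicate 1 (0.107) or 3 (0.0679). Pdgfrb stood at 0.317 and 0.166 CPM and did not pass.

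To ask how far sitagliptin returned the changes of high glucose toward NC, calls of both comparisons were set side by side. Slc1a4 and Tspoap1 had fallen in HG and rose in HG-SIG, and Trp53i11, Chst1 and Tmem38b had risen in HG and fell in HG-SIG. Tmem38b, an intracellular cation channel gene, went from 186 ± 16.5 CPM in NC to 432 ± 42.5 in HG and 156 ± 14.0 in HG-SIG (log2 fold changes 1.21 ± 0.08 and -1.47 ± 0.08). Slc1a4 stood at 10.6, 3.18 and 8.69 CPM in NC, HG and HG-SIG, Tspoap1 at 7.80, 3.09 and 7.29, Trp53i11 at 5.77, 18.3 and 7.46, and Chst1 at 5.42, 12.7 and 4.89. Other genes fell in both steps, among them Rgs16 (-2.56 and -4.33) and Myc (-2.88 and -3.46).

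**Figure D3:**
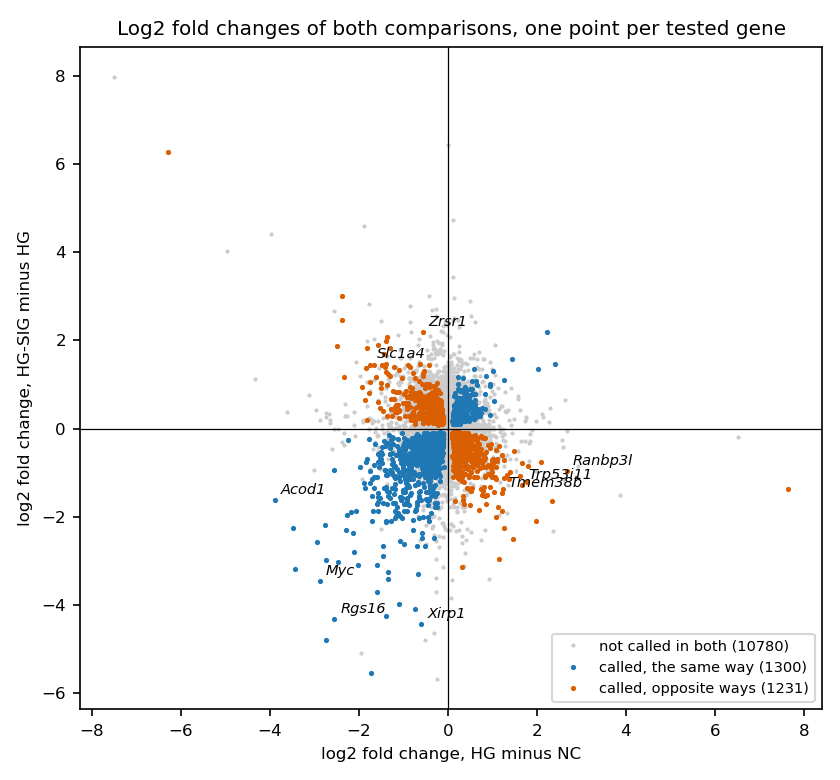
Log2 fold change of HG minus NC (horizontal) against HG-SIG minus HG (vertical) for the tested genes, with TMM scaling. Genes called in both comparisons are coloured, 1300 in the same direction and 1231 in opposite directions.

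Of 2531 genes called in both comparisons, 1231 (48.6%) went in opposite directions and 1300 in the same direction, a balance that depended on the setting. It was 1138 and 1684 by library size alone and 1088 and 1724 with limma on log2(TPM + 1). Opposite calls were the more frequent without HG replicate 3 (1437 and 1154) and with the GC and length trend removed (1455 and 1424), and without NC replicate 2 the split was even (1153 and 1152). The numbers that follow are those with TMM. Genes that rose in HG and fell in HG-SIG numbered 748, against 509.6 for independent lists, and genes that fell and then rose 483, against 520.6. Genes that rose in both steps numbered 442, against 487.5, and genes that fell in both 858, against 544.2. In 50 simulated sets of unchanged groups that shared the HG libraries, at most 1 gene was called in opposite directions and 0 in the same. Those sets held no changed gene, so few p-values could pass the adjustment. Their counts therefore do not show how many opposite calls sharing gives beside real changes. The correlation of the log2 fold changes across genes, which are not independent replicates, was r = -0.017, where sharing the HG libraries alone gave -0.519 (range -0.593 to -0.462). The covariance was -0.0039, against a simulated -0.0185 (range -0.0221 to -0.0158), a difference of 0.0146. With same-numbered libraries correlated as measured, the simulated covariance was -0.0113 (range -0.0155 to -0.0089). Among the 10205 genes with an average log2 CPM of 2 or more the correlation was 0.136 and the covariance 0.0152, against a simulated covariance of -0.0031, or -0.0019 with correlated libraries. The 3 HG libraries cannot be split into separate sets of 2 or more, so part of the excess of genes that rose and then fell may come from sharing them. Sharing gave a negative correlation and so does not account for the excess of genes that fell in both. The counts for independent lists take every gene as equally likely to be called, whatever its level. How far that adds to both excesses was not tested.

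HG-SIG was compared with NC to ask where sitagliptin-treated cells stood against the control. Inflammatory, macrophage and osteoclast genes were lower than in NC. Rgs16 went from 193 ± 9.39 to 1.63 ± 0.275 CPM (SD, n = 3; log2 fold change -6.89 ± 0.08 SE, adjusted p = 3.2e-14). Myc went from 18.9 ± 1.66 to 0.230 ± 0.0864 CPM (-6.35 ± 0.20) and Acod1 from 55.4 ± 1.15 to 1.21 ± 0.245 CPM (-5.51 ± 0.12). Of the 13311 genes 7801 were called, 3978 higher and 3823 lower in HG-SIG, and 1133 changed by more than 1 on the log2 scale, 388 up and 745 down. The libraries did not overlap for 66% of genes, where chance gives 10%. Il13ra2 (-5.30), Xirp1 (-5.05), Lilr4b (-4.96), Tnfsf8 (-4.85) and Pkd1l2 (-4.57) were also among the 8 lowest within the same limits. The 8 highest were the cyclooxygenase gene Ptgs1 (1.93), Grtp1 (1.91), Mob3b (1.84), Ranbp3l (1.70), Zrsr1 (1.62), the linker histone H1f2 (1.62), the MAX partner Mxd4 (1.62) and L3mbtl3 (1.60).

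Tnf stood at -2.51 ± 0.06 (SE) on the log2 scale relative to NC, and Nos2, with 67 counts in NC and 0 in HG-SIG, was at least 20.2-fold lower by the counting interval and 25.5-fold against the floor. Il10 had 37 and 3 counts, a ratio of NC over HG-SIG of 14.1 with an interval of 4.47 to 71.5, and Arg1 6 and 0, with an interval that starts at 1.35. All 24 NF-kB targets were lower than in NC (median log2 fold change -1.13, camera adjusted p = 2.6e-26, adjusted p = 7.9e-04 with an estimated correlation). The same held for 26 of 28 interferon-stimulated genes (median log2 fold change -1.49, camera adjusted p = 2.6e-26, adjusted p = 0.0182 with an estimated correlation). Lower too were 27 of 27 ATF4 targets (median log2 fold change -0.48, camera adjusted p = 1.3e-09, adjusted p = 0.0139 with an estimated correlation). Of the M1-type markers 10 of 12 fell and 1 rose (median log2 fold change -2.44, camera adjusted p = 1.3e-09, adjusted p = 0.0197 with an estimated correlation). Of the M2-type markers 8 of 10 fell and 2 rose (median log2 fold change -0.98, camera adjusted p = 7.3e-05, adjusted p = 0.0182 with an estimated correlation). Macrophage identity markers (17 of 19 lower, 1 higher, median log2 fold change -0.88, camera adjusted p = 4.4e-21, adjusted p = 7.9e-04 with an estimated correlation) were lower too. So were osteoclast markers (9 of 9 lower, median log2 fold change -2.06, camera adjusted p = 6.6e-16, adjusted p = 0.00133 with an estimated correlation). Of the unfolded protein response genes 21 of 21 were lower (median log2 fold change -0.57, camera adjusted p = 8.5e-13, adjusted p = 0.00984 with an estimated correlation). Cholesterol synthesis genes, 4 higher and 12 lower of 23, did not pass as a list (median -0.10, 0.09 when scaled by library size alone with 9 up and 5 down, camera adjusted p = 0.383). Over all 30 lists tested, 0 were higher and 15 lower with TMM, of which 12 held with an estimated correlation. By library size alone the cell cycle list passed as higher (adjusted p = 0.0398, 25 up and 1 down, against 14 and 11 of 35 with TMM). The NRF2 list passed as lower without HG-SIG replicate 1 (0.0408) or without a filter (0.0233), and the NFAT5 list without a filter (0.0233). Cytosolic ribosomal protein genes passed as lower with TMM (camera adjusted p = 0.0063). They no longer passed with an estimated correlation (0.658) or with the GC and length trend removed (0.0916). Scaled by library size alone the median of all genes moved up by 0.21 on the log2 scale and 76.2% of 8906 calls were higher (6786 up, 2120 down), against 51% with TMM; with limma on log2(TPM + 1) the shift was 0.23 and 80.2% were higher.

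Some of the named genes share sequence with close relatives or overlap another gene, so their counts are uncertain. Lilr4b, Hspa1b, Lyz1, Eno1b, H1f2, H2bc4 and Ifit2 have near-identical relatives between which reads could be split. Ccna2, Ctsd, Cxcl16, Dusp5, Fdft1, Gpr84, Hip1r, Hmgcs1, Irf5, Nfkb2, Pfkm, Rarb, Rgs16, Rpl5, Sqstm1, Tgm2 and Txnip overlap another gene of the table over more than 10% of their exonic length.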

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

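Scaling by library size alone, removing the trend with GC content and length, thinning and leaving out the unannotated loci were chosen after seeing the data. Under the other scalings, tools, filters and corrections each count of called genes stayed within 1.5 times the value given. Leaving out 1 library gave 3062 to 4000 calls in HG against NC, 6193 to 7147 in HG-SIG against HG, 7106 to 8191 in HG-SIG against NC and 947 to 1437 opposite calls. The lowest values came without NC replicate 1, except in HG-SIG against HG, without HG replicate 2, and the highest without HG replicate 3. At an adjusted p under 0.01, 2498 genes were called in HG against NC and 680 in opposite directions. Requiring also an absolute log2 fold change over 1 left 379, 706 and 1133 genes in the 3 comparisons and 47 in opposite directions, fewer by construction. With the replicate block the counts were 4663, 7563, 8282 and 1559, and 17 of 18 best matches between libraries of different groups were to the same number. These matches include NC libraries, so the model without the block may leave out a pairing in HG against NC. In HG-SIG against HG, where the numbers pair the libraries, the block changed the calls of Ccrl2 and Txnip and of no other gene or list named.

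In HG-SIG against HG the calls of polarization markers depended on the setting. M1-type markers (adjusted p = 0.0555) passed with an average log2 CPM of 1 or more (0.022) and by library size alone (0.0168), and ranged from 0.0402 to 0.12 as each library was left out. M2-type markers (0.0399) did not pass with an estimated correlation (0.205), without a filter (0.0655) or with the GC and length trend removed (0.0793), and ranged from 0.0232 to 0.0587. Of 90 list results 63 kept direction and side of the threshold under all alternatives, 27 changed side under at least 1, most often the estimated correlation, and 0 turned direction past the threshold. Of 242 results for named genes 229 kept both and 13 did not. In HG-SIG against HG 3 turned sign, none past the threshold: Akt1 by library size alone (0.01) and limma on log2(TPM + 1) (0.06), Slc6a6 under the same settings (0.00 and 0.05) and Tgfb1 under limma (0.04). These scalings shift all log2 fold changes of this comparison up, by 0.17 and 0.19 at the median. The other causes were not tested. Depth limits Il6, Arg1, Mrc1, Cd86, Il10 and Il1b, whose ratios have wide counting intervals or, for Il6, cannot be given.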

Other observations

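The tests of exchanged labels, of the covariance, of the ratio among genes that rose, of ERK output and of correlated same-numbered libraries were chosen after the result was seen, as were the removal of GC and length trends, thinning and scaling by library size as settings. The terms for exchanged labels, ERK output, the covariance, MYC targets and the ratio among genes that rose were made stricter after their values were seen.

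The transcription factor Myc, of the immediate-early list, fell at each step, from 18.9 ± 1.66 CPM in NC to 2.57 ± 0.635 in HG and 0.230 ± 0.0864 in HG-SIG (SD, n = 3), while Mxd4, which competes with MYC for MAX, stood at 7.86, 11.5 and 24.2 CPM. The p53 list member Sesn1 had 42.5, 91.6 and 55.0 CPM. An unannotated locus chosen after its values were seen had 938 counts in NC, 717 in HG and 17 in HG-SIG.

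NF-kB targets were lower in HG than in NC, opposite to what an inflammatory effect of glucose would give. An exchange of the NC and HG labels stays open: 4 osmolyte genes, chosen after values were seen, had a median log2 fold change of 0.78, but the NFAT5 list they belong to went both ways (5 up and 4 down of 15, camera adjusted p = 0.692). In HG-SIG, with the same stated glucose as HG, Slc5a3, Slc6a12 and Akr1b3 lay closer to NC than in HG. Their log2 fold changes against NC were 0.28 (Slc5a3), 0.60 (Slc6a12) and 0.10 (Akr1b3), so they did not follow the stated glucose alone. Slc6a6 did not move toward NC, with 0.05 in HG and -0.11 in HG-SIG. Scaling is argued against by the highest list median over 4 scalings, -1.06, and GC or length bias by a median of -1.10 after its removal. With no osmotic control and no stated glucose concentration or time for NC, glucose, osmolality and handling of the medium stay open as sources, and a difference in the NC culture could also produce it.

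More genes were called in HG-SIG against HG than in HG against NC. The ratio of the counts was 1.61 with GC and length trends removed, at least 1.74 over 4 scalings and 1.80 after thinning to the lowest library total, which argues against each of these as the whole cause. A larger effect of sitagliptin at 6 h than of glucose may account for it. The labels give 1 batch, and whether the groups were cultured side by side is not given in the sources used here. The 10 splits of 6 libraries cannot give a share under 0.05, the smallest being 0.1 (1 of 10). The real splits called 3502, 6673 and 8029 genes in HG against NC, HG-SIG against HG and HG-SIG against NC, and the highest of the other splits 0 in each, those that part all 3 numbered pairs of HG and HG-SIG included.

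A return of the changes of glucose toward NC was not seen across genes as a whole. It would put the covariance of the log2 fold changes below the simulated values, and the observed -0.0039 lay above all of them, also where same-numbered libraries were correlated as measured (-0.0155 to -0.0089). Among genes that rose in HG, 1.69 fell for each that rose again in HG-SIG, which first seemed to fit a return of these genes. The ratio was 1.78 among genes that had fallen in HG and 0.79 among genes not called, and once the comparison with fallen genes was required the test could not decide. A return of some groups, such as cholesterol genes and osmolyte genes other than Slc6a6, stays open.

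Lower MYC activity was tested as a hypothesis for the fall of Myc with 29 tested MYC target genes, 1 of which was in the fixed lists. In HG against NC their median was 0.08, with 8 up and 1 down, which speaks against lower MYC output at these genes as a set at this step. The 1 that fell, Odc1, had the largest change of the list (-1.49, from 1018 to 363 CPM, adjusted p = 2.3e-11), while the rises were at most 0.28. In HG-SIG against HG the list median was -0.25, with 23 of 29 down (camera adjusted p = 1.6e-05, adjusted p = 0.317 with an estimated correlation). This met the terms set before the value was seen. The further demand that all 4 scalings meet them was added afterwards and failed, with a median of -0.09 by library size alone, so the test leaves the hypothesis open. Log2 fold changes also fell with expression level in HG-SIG against HG (Spearman correlation -0.25). The part of that trend in the fall of the MYC targets was not tested.

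Weaker ERK signalling stays open as a candidate explanation for lower Myc in HG: 15 of 16 tested ERK output genes fell against NC, with a median of -0.93 (camera adjusted p = 6.3e-28, adjusted p = 3.4e-04 with an estimated correlation). Of these genes 8 were in the fixed lists, so their fall had been seen. The other 8 had 7 down and a median of -0.76 (camera adjusted p = 1.3e-15, adjusted p = 0.00181 with an estimated correlation). Whether they fell through ERK or along with the inflammatory genes that were lower in HG was not tested. In HG-SIG against HG all 16 had a median of -0.13, with 5 up and 7 down (camera adjusted p = 0.0384, adjusted p = 0.198 with an estimated correlation), and 0.03 by library size alone. The 8 outside the fixed lists did not pass there (adjusted p = 0.0711), which leaves this step undecided.

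A weaker amino acid response in HG was tested as a hypothesis for the lower ATF4 targets, with 16 genes outside the fixed lists chosen before their values were seen, such as aminoacyl-tRNA synthetases. Their median was -0.30 in HG against NC, with 13 of 16 down (camera adjusted p = 7.5e-12, adjusted p = 0.00226 with an estimated correlation) and -0.31 to -0.28 over 4 scalings. This met the terms set before the values were seen, but many of these genes are driven by ATF4 themselves and would fall with lower ATF4 activity of whatever origin. The test was therefore judged void after its value was seen, and an amino acid cause stays open. In HG-SIG against HG their median was -0.03, with 6 up and 4 down, and 0.13 by library size alone. Whether fresh medium or its age differed between NC and HG was not tested, since nothing in the labels gives it.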
